A study of Homo sapiens with 4 samples.

How the data were processed

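HNF4A is a nuclear receptor transcription factor of the liver. HCCLM3 is an established human hepatocellular carcinoma cell line. Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers the DNA bound by a protein with an antibody, and a nonspecific IgG antibody gives the background. The series holds 4 libraries, 1 per group: HNF4A and IgG at high glucose, and HNF4A and IgG at low glucose. Per the labels' protocols, stable overexpression lines were made by lentiviral transduction, and libraries were amplified by 15 cycles of PCR and sequenced on an Illumina Genome Analyzer. The labels name neither the gene overexpressed in each library nor the glucose concentrations.

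Per the submitters' processing notes, the tools were bcl2fastq, Bowtie 1.1.2, MACS, DiffBind and HOMER, and the build was hg19. Their settings are not given in the sources used here. The authors deposited 3 tables of comparisons: HNF4A over IgG at high glucose, HNF4A over IgG at low glucose, and HNF4A at high over low glucose. Per the file headers, each row gives a region, a mean level, a level for each side, a fold, a p-value, a false discovery rate (FDR) and the closest gene. From the values, the levels are log2 scaled read numbers and the authors' fold is the log2 level of the first side minus that of the second. The authors' FDR equals a Benjamini-Hochberg adjustment of the deposited p-values over all 5326 regions. The tables are therefore not cut at a p-value or FDR threshold. How the regions were chosen is not given, and they may have been chosen by reads in these same libraries. All 3 tables list the same 5326 regions. Regions were 101 to 8704 bp long with a median of 1030 bp. The lowest start in the files is 0, so starts were taken as counted from 0 and are printed counted from 1.

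Without the log, each level was a whole multiple of 1 step per library, within 0.01, for 100% of the 5326 values of each library. Dividing by that step gave the reads behind each value and the relative library sizes: 1.10 for HNF4A at high glucose, 0.993 for IgG at high glucose, 1 for HNF4A at low glucose and 0.982 for IgG at low glucose. These are relative sizes, and the total depth is not given in the sources used here. No listed value lay below 1 read, so a listed 1 may stand for 0 or 1. IgG was listed at 1 read in 42 regions at high glucose and in 58 at low glucose. Which side of the table of HNF4A alone was which glucose level was settled by matching its reads to the other tables.

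With 1 library per group no model across conditions was fitted, and none of the differences has a replicate check. The main counts are those of the authors' FDR under 0.05, by direction. Log2 ratios of scaled reads were recomputed from the recovered reads and equal the deposited folds. They carry exact 95% intervals (Clopper-Pearson on the reads of 2 libraries). These intervals cover counting error only, since PCR copies without molecular identifiers are not independent molecules. An exact binomial test of the reads of 2 libraries, and an exact conditional test of whether the HNF4A over IgG ratio differed between the glucose levels, both 2-sided and Benjamini-Hochberg adjusted over 5326 regions, were added after the data were seen. They compare libraries, not conditions. The planned Fisher's exact test of direction at high against low glucose is given as its odds ratio without a p-value, since regions are not replicates.

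On simulated reads with the levels of the high glucose table, the test of 2 libraries called 63.0% of regions changed 2-fold, 100% of those changed 4-fold and 0.0975% of unchanged regions, over 5326 regions. The test of the difference called 25.0%, 86.0% and 0.0390% of the same classes. The simulated reads held counting error alone, with equal library sizes and no shift over all regions. These shares are therefore not error rates for the calls in the real libraries.

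The rule for named genes and 15 gene lists were fixed before the data were examined. Per comparison, the rule takes the 10 regions with the highest and the 10 with the lowest log2 fold, 1 per gene, at or above the table's median level (all regions, since fewer than 20 passed the FDR). It adds up to 4 members of each list with the largest absolute fold, HNF4A itself and each AMPK list member with a region. Not every gene that the rule names is reported here. A gene in a list is represented by its region with the highest mean level in that table. For IgG at high over low glucose and for the difference of ratios, it is the region with the highest mean HNF4A level. A list's difference can therefore rest on other regions than its medians over IgG. A list's median log2 fold is given with its percentile among 10000 random lists of the same size, matched on 10 bins of level, where at least 5 members had a region. This describes these libraries and is not a test of conditions.

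Genes are those the authors list as closest to each region; no distance is used, and closeness does not show regulation. Of 4323 symbols, 3943 matched a current symbol and 243 an older one in a table of GRCh38.p14 gene names, used for names only. No gene name was given for 33 regions, 7 regions carried a symbol turned into a date, and 20 regions had different symbols between tables. The planned motif search, genomic classes and distance limits need a genome or annotation of the build and were not run. Alternatives covered the FDR, a minimum fold, level filters, autosomes, centring, scaling, overlap and the treatment of IgG. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.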

Results

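The series asked which genes HNF4A occupies in HCCLM3 hepatocellular carcinoma cells at different glucose levels. HNF4A and IgG libraries were made at high and at low glucose, 1 library per group, and all values below are therefore without replicates. Over the same 5326 regions, HNF4A had 402237 reads at high glucose and 295460 at low glucose, and IgG had 249744 and 198683. The median region held 50 HNF4A reads at high glucose and 35 at low glucose, against 26 and 18 IgG reads. Ratios below are of reads scaled by relative library size, and the range after each is its exact 95% counting interval. Coordinates are hg19, and each gene is the one the authors list as closest. The highest and lowest regions of each comparison are given among regions at or above the median level of its table, and regions with fewer reads reached more extreme ratios.

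At high glucose, the regions with the highest HNF4A over IgG ratio, among those at or above the median level, lay nearest to SKIL, NDST1 and USP38. SKIL encodes a repressor of SMAD signalling, and its region (chromosome 3, 170048708 to 170049478) held 109 HNF4A reads and 3 IgG reads, a log2 ratio of 5.04 (3.45 to 7.34). The region of NDST1, an enzyme of heparan sulfate synthesis (chromosome 5, 149922113 to 149923252), held 132 and 5 reads, a log2 ratio of 4.58 (3.32 to 6.22). USP38, a deubiquitinase gene, followed at 4.31 (3.05 to 5.96). MOCOS, DUSP6, PRKG2, TBX15, NUCB1, RRAS2 and FAM110B completed the 10 highest, at log2 ratios from 3.61 down to 3.12. DUSP6, a phosphatase of ERK kinases, stood at 3.34 (2.41 to 4.44). In the same part of the regions by level, the lowest ratios lay nearest to XKR7, at -1.35 (-1.79 to -0.91), SYT7, at -1.19 (-1.84 to -0.57), and LOC101929116, at -1.04 (-1.75 to -0.37). ANKRD20A12P, SCRT1, HDX, ING5, NPAS4, CACNA1B and LOC283440 made up the rest of the 10 lowest, at -1.04 to -0.79.

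Across the 5326 regions at high glucose, HNF4A was higher than IgG in 4482 and lower in 844, with a median log2 ratio of 0.79. At least a 2-fold excess over IgG was seen in 2218 regions. If the regions were chosen by reads in these same libraries, an excess over IgG in most of them, at either glucose level, would be partly built in. In the authors' deposited table, 0 regions passed an FDR of 0.05 in either direction, and the lowest FDR was 0.173. The authors' deposited table held 264 regions with an unadjusted p under 0.05 above IgG and 1 below it. By chance 266 of 5326 would be expected over both directions together, so the total of 265 was near that number but its directions were uneven. The exact binomial test of the reads called 2784 regions higher and 85 lower, and it compares the 2 libraries only.

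At low glucose, the region nearest to ACSL5, which activates long-chain fatty acids, had the highest ratio among regions at or above the median level. It lay on chromosome 10 from 114139223 to 114140408 and held 57 HNF4A reads against 3 IgG reads, a log2 ratio of 4.22 (2.60 to 6.54). ENTPD8 followed at 4.09 (2.46 to 6.41), and the Integrator complex gene INTS1 at 3.59 (2.14 to 5.52). A region nearest to RPTOR, which encodes a scaffold of the mTORC1 complex, stood at 3.48 (2.18 to 5.16), on chromosome 17 from 78602909 to 78604029. SKIL and NDST1 were again among the 10 highest, at 3.30 (1.98 to 4.98) and 3.26 (2.21 to 4.52). ZNF778, LOC100507391, DNAH17 and LENG8 completed the 10, at 3.32 to 3.14. Within the same level limit, the lowest ratios lay nearest to IFT52, at -0.96 (-1.76 to -0.20), LOC441666, at -0.90 (-1.68 to -0.15), and SIK2, at -0.88 (-1.72 to -0.08). FANCG, ANKRD20A12P, NCAPG2, S100A7A, XKR7, TFEC and ARPC3 ranged from -0.82 to -0.57. XKR7 and ANKRD20A12P were among the 10 lowest at both glucose levels.

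HNF4A was higher than IgG in 4873 regions at low glucose and lower in 453, with a median log2 ratio of 0.94. The authors' deposited table held 0 regions at an FDR under 0.05, with a lowest FDR of 0.820. At an unadjusted p under 0.05, the authors' deposited table held 162 regions above IgG and 0 below, with 266 expected by chance over both directions together. The exact binomial test called 2718 regions higher and 31 lower between these 2 libraries.

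The log2 ratios over IgG at high and at low glucose come from separate libraries. Across regions, which are not independent replicates, they had a Pearson correlation of 0.561 and a Spearman correlation of 0.606. HNF4A was above IgG at both glucose levels in 4245 regions, at high glucose alone in 237, at low glucose alone in 628 and at neither in 216, an odds ratio of 6.16. Of the 264 and 162 regions above IgG at an unadjusted p under 0.05 in the authors' deposited tables, 43 were shared, where independent lists would share 8.03. Those 43 included SKIL, NDST1, RPTOR and ACSL5. They also included GPT, the alanine aminotransferase gene, with log2 ratios of 1.37 (0.98 to 1.77) at high and 1.94 (1.41 to 2.51) at low glucose.

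**Figure D1:**
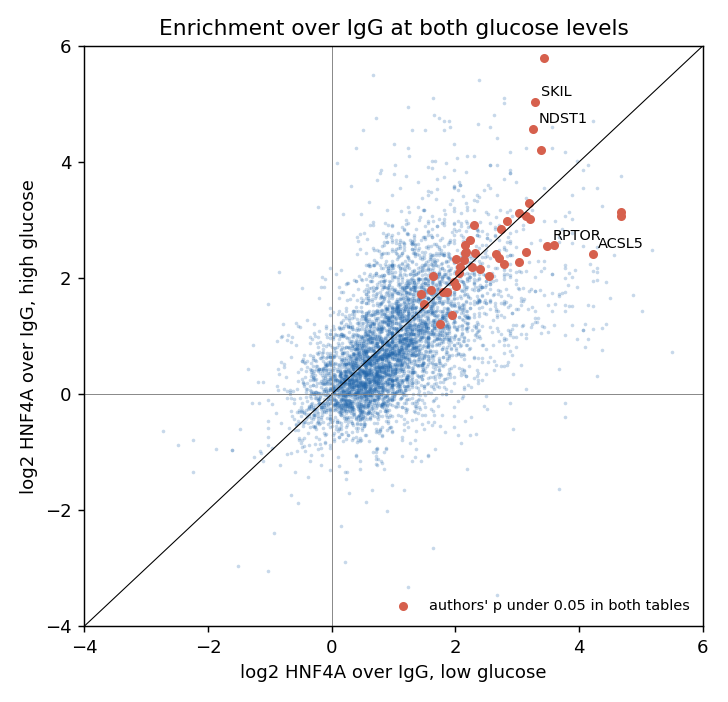
Each point is 1 of the 5326 regions, with the log2 HNF4A over IgG ratio at low glucose on the x axis and at high glucose on the y axis. Orange points are the 43 regions with an unadjusted p under 0.05 in both of the authors' deposited tables, and the diagonal marks equal ratios.

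Between HNF4A libraries, the region nearest to AHR, the aryl hydrocarbon receptor gene, was the one most in excess at high glucose among regions at or above the median level. It lay on chromosome 7 from 17138801 to 17139593 and held 98 reads at high and 22 at low glucose, a log2 ratio of 2.02 (1.34 to 2.76). RRAS2, a RAS-related GTPase gene, stood at 1.91 (1.33 to 2.53), and PTGIS, the prostacyclin synthase gene, at 1.78 (1.27 to 2.32). ABCC11, ISOC1, LOC100289230, SIK2, POR, AWAT1 and GPCPD1 followed at 1.76 to 1.61. SIK2 encodes a salt-inducible kinase of the AMPK-related family, and POR the electron donor of microsomal cytochromes P450. IgG was also higher at high glucose for POR, at 1.21 (0.02 to 2.52), and for LOC100289230, at 0.89 (0.12 to 1.68). In the other direction and within that limit, the largest excess at low glucose lay nearest to EMBP1, at -0.97 (-1.64 to -0.32), SYT7, at -0.92 (-1.59 to -0.28), and SUN1, at -0.73 (-1.21 to -0.25). EMBP1, ACTR3BP2 and ANKRD30BP2 are pseudogenes listed as closest to short regions, of 102, 108 and 213 bp. Reads in those regions may be shared with near-identical sequence elsewhere, which was not tested. ACTR3BP2, KCNK9, SPAG1, ANKRD30BP2, FITM2, ZHX3 and TFEC ranged from -0.71 to -0.55.

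HNF4A reads were higher at high glucose in 4357 regions and lower in 969, with a median log2 ratio of 0.36. After centring on that median the share of regions higher was 50% in place of 81.8%. The background moved in the same direction, since IgG was higher at high glucose in 4147 regions and lower in 1179, with a median of 0.51. Region by region, the HNF4A and IgG ratios of high over low glucose had a Pearson correlation of 0.00953 and a Spearman correlation of 0.0200. In the authors' deposited table for this comparison, 0 regions passed an FDR of 0.05 and the lowest FDR was 0.914. The authors' deposited table held 234 regions higher and 12 lower at an unadjusted p under 0.05, with 266 expected by chance over both directions together. The exact binomial test called 692 higher and 14 lower for HNF4A, and 759 higher and 51 lower for IgG. The HNF4A over IgG ratio was higher at high than at low glucose in 2222 regions and lower in 3104, a median difference of -0.15. That share of regions higher, 41.7%, became 31.1% when each pair was scaled on the top 1% of regions, which stood little above IgG. It turned to 55.8% when IgG was subtracted, and both alternatives were chosen after the data were seen. Where HNF4A exceeds IgG, a common rise of both would by itself raise the subtracted reads.

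**Figure D2:**
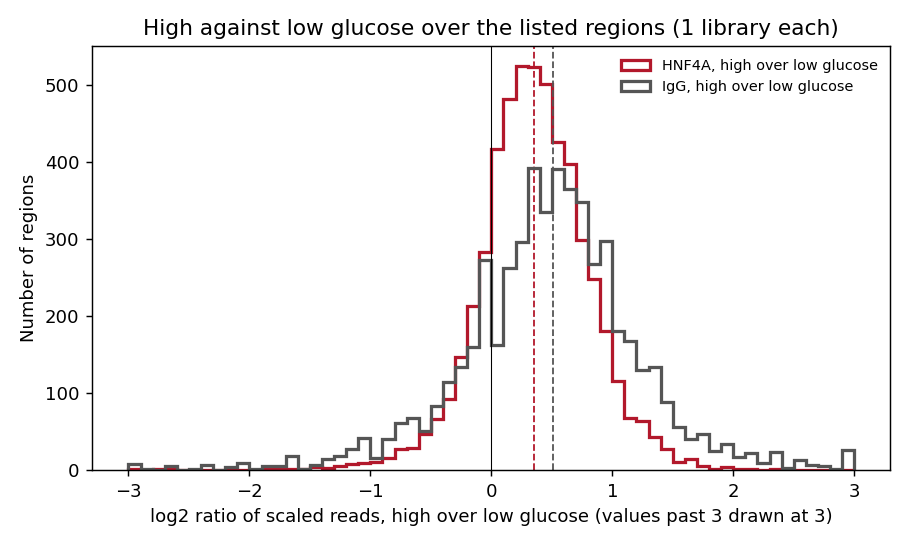
The number of regions (y axis) is plotted by the log2 ratio of scaled reads at high over low glucose (x axis), in red for HNF4A and in grey for IgG. Dashed lines mark the medians, 0.36 for HNF4A and 0.51 for IgG.

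List medians over IgG are read against the medians of all regions, 0.79 and 0.94. Those of glycolysis, of epithelial and mesenchymal markers, of bile acid and drug metabolism (3 members, at 0.78) and of blood and stromal genes (1 member, at 0.51) lay above 0 but below that reference at low glucose, and those of the AMPK, autophagy, and neuron and muscle lists at both glucose levels. Those of lipoprotein and cholesterol genes and of cell cycle and survival also lay below it at low glucose, but not with all regions of a gene averaged, at 1.29 and 0.94. Of the 15 gene lists, fatty acid metabolism had the highest medians over IgG. All 8 of its members with a region were above IgG at both glucose levels, with a median log2 ratio of 2.02 at high glucose, the 99.9th percentile of matched random lists, and 1.92 at low glucose, the 99.8th. CPT1A, which carries fatty acids into mitochondria, stood at 2.14 (1.09 to 3.36) at high and 3.93 (1.95 to 7.04) at low glucose. The nuclear receptor gene PPARG stood at 1.98 (1.12 to 2.93) and 2.30 (1.30 to 3.44). CD36, a fatty acid transporter gene, stood at 2.14 (1.40 to 2.96) and 1.46 (0.58 to 2.42). In the authors' deposited table for low glucose, 0 of the 8 passed the FDR over all regions and 1, ACSL5, passed when adjusted over the list alone, at 0.0129. Between HNF4A libraries the list had a median of 0.40 against 0.36 for all regions. For IgG it had a median of 0.80 (percentile 89.7). The HNF4A over IgG ratio was lower at high than at low glucose in 7 of the 8. The median difference was -0.44 (percentile 15.2), against -0.15 over all regions.

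Among liver transcription factors, all 10 members with a region were above IgG at both glucose levels, with medians of 1.0 and 1.14 (percentiles 71.8 and 73.4). HNF4A itself had a region on chromosome 20 from 43029574 to 43030526, with 43 HNF4A and 25 IgG reads at high glucose, a log2 ratio of 0.64 (-0.11 to 1.41). At low glucose its ratio was 1.02 (0.14 to 1.94), and HNF4A at high over low glucose was 0.16 (-0.52 to 0.85). NR1I2, the pregnane X receptor gene, stood at 2.02 (1.01 to 3.18) over IgG at high and 0.83 (-0.10 to 1.81) at low glucose. Of lipoprotein and cholesterol genes, 10 of 10 were above IgG at high and 9 of 10 at low glucose, with medians of 1.29 and 0.91 (percentiles 86.9 and 25.7). LIPC, the hepatic lipase gene, stood at 2.81 (1.31 to 4.77) and 1.56 (0.03 to 3.37). All 10 of these held more HNF4A reads at high glucose, led by APOE at 1.09 (0.48 to 1.74). Their median was 0.63 (percentile 94.3), or 0.28 after centring on the median of all regions, and for IgG it was 0.34 (percentile 17.9). The HNF4A over IgG ratio was higher at high glucose in 7 and lower in 3, with a median difference of 0.38 (percentile 96.7). Of hepatocyte secreted proteins, 6 had a region, with medians over IgG of 1.16 and 1.36 (percentiles 74.0 and 77.1). AGT, the angiotensinogen gene, stood at 1.25 (0.68 to 1.85) for HNF4A at high over low glucose and at 1.18 (0.23 to 2.20) for IgG. Bile acid and drug metabolism had 3 members with a region, 2 of them above IgG at high glucose and 3 at low glucose, among them CYP27A1 at 1.12 (0.57 to 1.70) at high glucose.

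For glycolysis, 11 members had a region, all 11 above IgG at high glucose and 10 at low glucose, with medians of 1.09 and 0.82 (percentiles 90.3 and 33.9). All 11 held more HNF4A reads at high than at low glucose, with a median of 0.59 (percentile 95.1), or 0.24 after centring on the median of all regions, and 6 had an interval above 0 before centring. These included SLC2A2, the glucose transporter gene, at 1.38 (0.51 to 2.34), LDHB at 1.03 (0.32 to 1.79) and MLXIPL, which encodes a carbohydrate-responsive transcription factor, at 0.78 (0.28 to 1.29). For IgG the same list had a median of 0.40 (percentile 20.3), with 9 of 11 higher at high glucose. The HNF4A over IgG ratio of the list was higher at high glucose in 6 members and lower in 5. Its median difference was 0.34 (percentile 98.0) and its mean difference 0.17, against a median of -0.15 over all regions. None of its members passed the FDR in the authors' deposited tables, over all regions or adjusted over the list alone. Gluconeogenesis and glycogen had 4 members with a region, all above IgG at both glucose levels. In the authors' deposited table for low glucose, 1 of the 4, GPT, passed when adjusted over the list alone, at 0.0400.

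Of the AMPK and mTOR pathway, 13 members had a region, 10 above IgG at high glucose and 12 at low glucose. The medians were 0.25 (percentile 5.10) and 0.69 (percentile 23), which turn to -0.54 and -0.25 after centring on the medians of all regions. CAMKK2, which encodes a kinase upstream of AMPK, stood at 1.33 (0.89 to 1.79) at high and 2.06 (1.49 to 2.68) at low glucose. EIF4EBP1, a target of mTORC1, stood at 2.37 (1.19 to 3.77) and 2.11 (0.67 to 3.87). PRKAA2, the AMPK alpha 2 subunit gene, had 21 HNF4A reads and a listed 1 IgG read, which may stand for 0, at high glucose, a ratio of 4.25 (1.61 to 9.62), and 0.39 (-0.98 to 1.81) at low glucose. The AMPK gamma subunit gene PRKAG2 had the highest ratio of the list for HNF4A at high over low glucose, at 1.04 (0.57 to 1.52), on chromosome 7 from 151441727 to 151443025, where IgG stood at 0.71 (-0.08 to 1.52). Over the 7 regions of PRKAG2 the median was 0.59 for HNF4A and 0.72 for IgG. Only PRKAG2 and AKT1S1, at 0.44 (0.04 to 0.84) where IgG stood at 0.69 (0.23 to 1.17), had an interval above 0 in that comparison, and the list median was 0.32 (percentile 36.0), or -0.04 after centring on the median of all regions. For IgG at high over low glucose the same list had a median of 0.66 (percentile 75.8), with 12 of 13 members higher. The HNF4A over IgG ratio was higher at high glucose in 3 members and lower in 10, with a median difference of -0.25 (percentile 33.3). RPTOR was represented over IgG by its region of highest level (chromosome 17, 78573060 to 78574618), at 0.21 (-0.31 to 0.73) and 0.86 (0.16 to 1.59), unlike its other region above, and PRKAG2 at low glucose by the region from 151504732 to 151506092, at 0.57 (-0.11 to 1.28). STK11, the gene of the AMPK-activating kinase LKB1, stood at 0.25 (-0.34 to 0.85) and 0.47 (-0.28 to 1.23) over IgG. RICTOR stood at -0.54 (-1.41 to 0.30) and 1.75 (0.49 to 3.21). PRKAB2, PRKAG1, STRADA, TSC1 and ULK1 ranged from -0.27 to 0.67 over IgG at high glucose, and each interval there included 0. At low glucose PRKAB2 stood at 0.69 (0.30 to 1.09), and the intervals of the other 4 included 0.

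**Figure D3:**
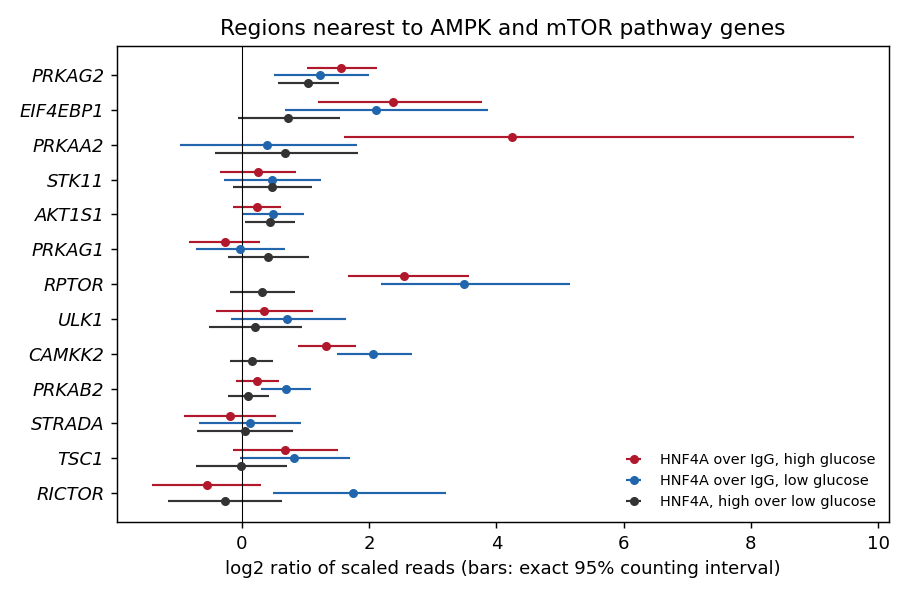
Points are log2 ratios of scaled reads (x axis) for the region representing each AMPK and mTOR pathway gene (y axis) in the high over low glucose table, with 1 library per group, and bars are exact 95% counting intervals. The ratio of HNF4A at high over low glucose has an interval above 0 for PRKAG2 and AKT1S1.

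Of the remaining lists, the Wnt pathway had 12 members with a region, all above IgG at both glucose levels, with medians of 1.12 and 1.06 (percentiles 85.5 and 59.3). AXIN2 stood at 1.22 (0.58 to 1.89) for HNF4A at high over low glucose, where the list median was 0.58 (percentile 94.4), or 0.23 after centring, and 0.48 (percentile 39.0) for IgG. The HNF4A over IgG ratio of the Wnt list was higher at high glucose in 6 members and lower in 6, with a median difference of -0.12 (percentile 58.1). With all regions of a gene averaged, its median over IgG at low glucose moved from 1.06 to 1.44. Cell cycle and survival had 10 members with a region, with medians over IgG of 0.88 and 0.77 (percentiles 80.6 and 38.5). A region nearest to MYC stood at 2.47 (1.65 to 3.40) over IgG at high and 0.97 (0.12 to 1.88) at low glucose. Epithelial and mesenchymal markers had 7 members with a region, all above IgG at both levels, with medians of 1.1 and 0.87 (percentiles 86.6 and 50.4), among them SNAI2 at 1.99 (1.24 to 2.81) and 2.0 (1.11 to 3.00). Inflammation and NF-kB had 7 with medians of 1.2 and 1.45 (percentiles 65.9 and 84.6). Autophagy and lysosome had 9 with medians of 0.23 and 0.76 (percentiles 7.58 and 34.9), and LAMP2 stood at 1.65 (0.90 to 2.47) and 1.33 (0.47 to 2.26). A region was listed for 2 of 25 neuron and muscle genes, MYOD1 and SYP, and for 1 of 24 blood and stromal genes, COL1A2. The counts were 3 of 29 for bile acid and drug metabolism, 6 of 41 for hepatocyte secreted proteins, 10 of 29 for liver transcription factors, 11 of 26 for glycolysis, 13 of 32 for the AMPK and mTOR pathway and 12 of 28 for the Wnt pathway, and 18.2% of protein-coding genes were closest to a region. These shares were not tested against each other.

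One stretch with many reads in all 4 libraries had low median ratios over IgG. From TES to CAPZA2 on chromosome 7 (115849041 to 116505281), a stretch that holds CAV1, CAV2 and the receptor tyrosine kinase gene MET, 16 regions had a median of 253 HNF4A and 201 IgG reads per kb at high glucose, and 208 and 214 at low glucose. Their median log2 ratios over IgG were 0.25 and 0.03. Single regions stood higher, the highest at high glucose being 1 nearest to TES, at 1.69 (1.40 to 1.99), with 0.59 (0.28 to 0.91) at low glucose. The rest of chromosome 7 had medians of 0.66 and 0.73 over IgG.

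**Figure D4:**
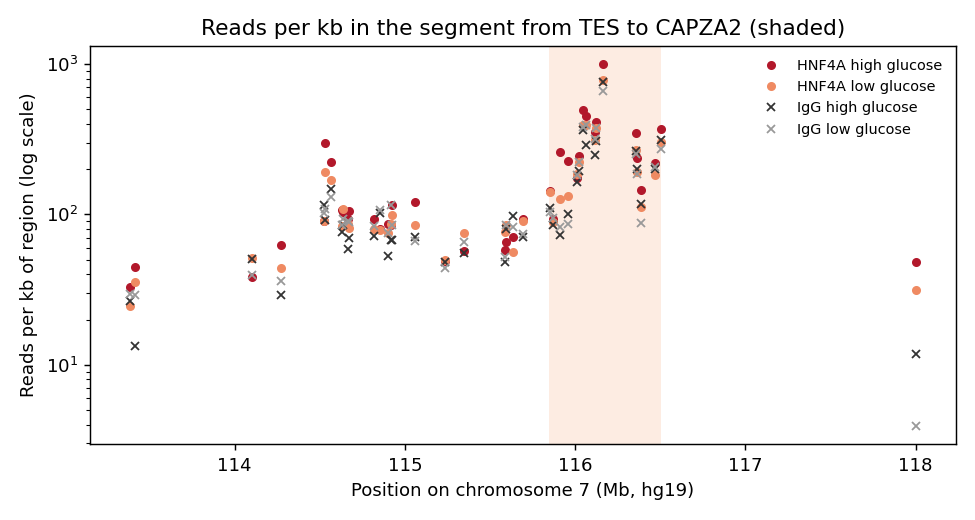
Reads per kb of region on a log scale (y axis) are plotted by position on chromosome 7 in Mb (x axis) for the 4 libraries, with circles for HNF4A and crosses for IgG. In the shaded stretch from TES to CAPZA2 the medians were 253 and 208 for HNF4A, and 201 and 214 for IgG, at high and low glucose.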

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

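The test of the difference between glucose levels, and each test of an explanation given here, was chosen only after the result was seen. By the exact conditional test of reads, adjusted over 5326 regions, the HNF4A over IgG ratio differed between the glucose levels in 69 regions, 31 higher and 38 lower at high glucose. Of the 31, 15 were among the 54 regions with the most HNF4A reads and 4 lay in the chromosome 7 stretch described below, against 4 and 0 of the 38. The test compares 4 single libraries, not conditions. Of the genes named by the fixed rule, USP38 differed by 3.31 on the log2 scale, AHR by 2.24, SIK2 by 1.8 and SYT7 by -2.0, with adjusted p of 0.000499, 0.0465, 0.0310 and 0.00161. For USP38, IgG reads were 5 at high and 21 at low glucose, so IgG enters the difference. For AHR and SIK2 the IgG log2 ratio of high over low glucose was -0.22 (-1.41 to 0.95) and -0.13 (-0.84 to 0.57). For SYT7, IgG stood at 1.07 (0.45 to 1.73) and HNF4A at -0.92 (-1.59 to -0.28). In the 38 regions lower at high glucose, the median log2 ratio of high over low was -0.20 for HNF4A and 1.48 for IgG, and in the 31 higher it was 0.88 and -0.38.

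HNF4A reads were higher at high glucose in 81.8% of regions. A wrong factor for library size would move every region alike. The 1% of regions with the most reads argue against it as the whole cause, with a median log2 ratio of 0.0682 against 0.36 over all regions. Those 54 regions were unlike the rest, with median log2 ratios over IgG of 0.22 at high and -0.01 at low glucose. Of the 54, 14 lay in the chromosome 7 stretch described below. The region with the most reads lay nearest to the pseudogene EMBP1, with 18380 HNF4A and 17159 IgG reads at high glucose. The 54 regions held 27.3% of the IgG reads of all listed regions at high and 35.5% at low glucose, against 19.9% and 23.4% for HNF4A. Their IgG median at high over low glucose was -0.16, so they are not a neutral measure of the factor. Scaled IgG reads were also higher at high glucose, with a median of 0.51 over all regions. Both high glucose libraries thus held a larger share of reads in the 5326 regions. This restates the pattern with IgG included and does not give its cause. More HNF4A-specific signal at high glucose stays open. The median log2 HNF4A over IgG ratio was lower at high glucose, by -0.15. The median of scaled reads left after subtracting IgG was 18.4 at high and 16.2 at low glucose. A common rise of HNF4A and IgG reads would also raise the reads left, so the subtraction cannot decide the question. With 1 library per group, glucose and library cannot be told apart.

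The stretch of chromosome 7 from TES to CAPZA2 held 14 of the 54 regions with the most HNF4A reads. HNF4A binding as the cause over the stretch as a whole is argued against by the higher of its median log2 ratios over IgG, 0.25, since the upper quartiles of 0.32 and 0.25 at high and low glucose lay below the medians of all regions, though single regions near TES stood at 1.69 and 1.02 at high glucose. Extra DNA copies may account for it, as a hypothesis, since both IgG libraries had more reads per kb there than on the rest of the chromosome, by 6.90 times at high and 10.5 times at low glucose. Without the 1% of regions with the most HNF4A reads, which leaves 2 regions of the stretch, the ratios were 3.80 and 4.37. The stretch was picked for its HNF4A reads, with bounds redrawn after a wider one had been tried and its values seen, and DNA copy number was not measured.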

How the results depend on the processing

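The unadjusted p, the exact test of reads, scaling on the top 1%, the subsets above IgG and the subtraction of IgG were chosen after seeing the data. The count of regions past the authors' FDR was 0 in each direction of each comparison. It stayed 0 when re-adjusted at or above the median level, without the 1% with the highest level and on autosomes only. An FDR of 0.01 or a log2 fold of at least 1 also gave 0, but such stricter limits could not have given more. By sign alone the counts higher and lower were 4482 and 844 over IgG at high glucose, 4873 and 453 at low glucose, and 4357 and 969 for HNF4A at high over low glucose. At an unadjusted p under 0.05 in the authors' deposited tables they were 264 and 1, 162 and 0, and 234 and 12. By the exact test of reads they were 2784 and 85, 2718 and 31, and 692 and 14; it assumes counting error alone. The share of regions higher, 84.2%, 91.5% and 81.8% in the 3 comparisons, became 97.5%, 99% and 90.5% with a log2 fold of at least 1, and 83.0%, 90.6% and 88.2% at or above the median level. For HNF4A at high over low glucose it became 50% after centring, by construction, and 76.7% when scaled on the top 1%. The top 1% stood little above IgG and is not a neutral reference. In regions with an unadjusted p under 0.05 above IgG at either level the share was 88.8%. Those regions were picked by the same HNF4A reads that the ratio compares, more of them at high glucose, so that rise may be built in. The share of regions with more HNF4A over IgG at high than at low glucose was 41.7% as a ratio and 31.1% when scaled on the top 1%. It turned to 55.8% when IgG was subtracted, and the cause was not tested. Where HNF4A exceeds IgG, a common rise of both would also raise the subtracted reads. Shared regions above IgG numbered 43, also at 50% reciprocal overlap, and 46 by gene symbol. Averaging all regions of a gene kept 44 of 45 list medians within counting error, among them lipoprotein genes at low glucose, from 0.91 to 1.29, and moved that of the Wnt pathway at low glucose from 1.06 to 1.44, and centring turned the sign of 16 of 45. The planned limit to regions past the FDR above IgG left no region. Distances to start sites, genomic classes and motif content were not run. HNF4A over IgG was compared across the glucose levels by the difference of log2 ratios and the exact conditional test of reads. No analysis paired by replicate was run, since each group had 1 library. Depth limits single regions: medians of 18 and 26 IgG reads leave wide intervals.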

Other observations

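The genes and groups named here were chosen after their values were seen. Besides the genes named above, the 43 regions above IgG at an unadjusted p under 0.05 in both of the authors' deposited tables lay nearest to PPP2CB, a catalytic subunit gene of protein phosphatase 2A, with log2 ratios of 5.78 (3.25 to 11.1) at high glucose, against a listed 1 IgG read that may stand for 0, and 3.43 (1.98 to 5.37) at low glucose, and to the phosphatase gene DUSP10, at 3.29 and 3.18. Others were KDM6B, a histone demethylase gene, at 2.41 and 2.66, GCLC, which encodes a subunit of the enzyme that starts glutathione synthesis, at 2.30 and 2.14, BCL9L, a cofactor gene of beta-catenin, at 1.92 and 1.97, and LGALS3BP at 2.43 and 2.32. HNF4A at high over low glucose stood at 0.68 (0.07 to 1.30) for DUSP10, 0.53 (0.09 to 0.98) for LGALS3BP and 0.40 (0.05 to 0.75) for BCL9L. It stood at 0.34 for PPP2CB, 0.24 for GCLC and -0.01 for KDM6B, with intervals that included 0.

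PRKAG2 and TRIB1, a pseudokinase gene, were each closest to 7 regions, with median log2 ratios over IgG of 0.68 and 1.13 at high glucose and 1.1 and 1.43 at low glucose. Chromosome 13 had 3 regions, against 498 on chromosome 7 and 496 on chromosome 12. Their median IgG reads per region at high glucose were 2, 37 and 37. Their median log2 ratios over IgG at high glucose were 3.44, 0.64 and 0.65. Background thus differed between these chromosomes, and neither the rankings of regions nor the list percentiles took account of chromosome. The standard deviation of the log2 ratio of high over low glucose across regions was 0.46 for HNF4A and 0.75 for IgG, where counting error alone gave 0.35 and 0.56 in 20 simulated draws.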
